A study of Mus musculus with 10 samples.

How the data were processed

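Total RNA of mouse retina was sequenced in 10 libraries, 5 of a light-induced damage model and 5 controls. Groups and replicate numbers were taken from the sample titles in the labels. Per the labels, RNA was purified on spin columns from homogenised tissue, and all libraries carry the same batch entry. The labels do not say whether the libraries mark strand, so reads of a gene and of an antisense partner may not be told apart.

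The deposited table holds 1 count per gene and library, as whole numbers, for 19999 genes. The submitters' processing notes name Bowtie2, RSEM 1.3.1, DESeq2 1.4.5 and the genome build GRCm39, without saying in which step each was used. Whether the deposited counts are rounded RSEM estimates, and how reads shared by near-identical genes were divided, is not given in the sources used here. Counts of close paralogs, such as the crystallin genes, are therefore uncertain. Of the genes in the table, 36 had a count of 0 in every library. Gene symbols came from GENCODE M21 by Ensembl identifier, and 19892 identifiers matched. Sting1 appears there under an older symbol, and a list gene whose symbol belongs to 2 identifiers was taken from the lower identifier. That annotation belongs to GRCm38, so it was used for names, gene classes, transcript length and GC content, and no coordinates are printed. Lengths and GC content are those of the longest annotated transcript. All deposited columns belong to these libraries.

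Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr with its default settings, which left 16852 genes holding between 99.804% and 99.924% of the counts of a library. Library totals were scaled by TMM. Light damage was compared with control by the edgeR quasi-likelihood test with robust dispersion, with group as the single term and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was derived from that test's F statistic. CPM values are TMM scaled, and log2 CPM used a prior count of 2. With 5 libraries per group an exact permutation test cannot give a two-sided p below 0.00794, and with 3 against 5 none below 0.0179.

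Gene lists were written before the data were examined, 37 in all, for pathways named by the series title, retinal cell types, tissues that a retinal dissection can carry, and stress, death and immune responses. Of these, 34 had at least 5 tested genes. They were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 34 lists, then with an estimated correlation and with fry. A list score is the mean over its genes of log2 CPM, centred over all 10 libraries. An exact two-sided permutation test of these scores, adjusted over the 34 lists, was chosen after seeing the data.

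Genes named in the text followed a rule fixed before the data were examined. They are P2rx7, Cgas and Sting1, then the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 1 CPM, a symbol that is not a gene model, and no overlap between the groups. For each list described, up to 4 members with the lowest p were added, with called members of the opposite direction. Genes outside the rule, apart from Xist, are named as such.

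Alternatives fixed before the data were examined were DESeq2, limma-voom, other scalings, other filters on low counts, a fit without robust dispersion, a test against a log2 fold change of 0.5 with glmTreat, the replicate number as a block, and leaving out each library in turn. Chosen after seeing the data were fits without the high-Xist libraries or with a term for them, a fit with the lens score as a covariate, and a fit that removed each library's trends with GC content and transcript length by lowess with a span of 0.3. The groups were also compared with 100 of the 126 splits of the 10 libraries into groups of 5. No pair of libraries held the same values, and chi-square statistics per degree of freedom lay above 6 for every pair, so each library counts once.

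The steps were tested on simulated counts for these 16852 genes in 5 against 5 libraries, with 200 genes changed. Of genes changed 1.5-fold 64.2% were recovered, of those changed 2-fold 89.6% and of those changed 4-fold 97.0%, with 10 false calls and no wrong direction. With no gene changed, 1 gene and no list was called. Changed genes were drawn only from those above a minimum mean expression, so these rates do not cover genes with low counts. Each gene was simulated independently, so the absence of list calls does not cover lists whose genes vary together. All libraries of a group were simulated from the same mean per gene, so the rates do not cover a group made of unlike libraries. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.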

Results

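Retinal RNA was sequenced from BALB/c mice, an albino laboratory strain, in a light-induced damage model and in controls. Each group held 5 libraries, and the library names of both groups carry the word vehicle. The series title concerns the purinergic receptor P2rx7 and cGAS-STING signaling, and the design text names a treatment, A74, whose libraries were not analysed here. The comparison made here asks how the transcriptome of the light-damaged retina differed from that of control retina. The deposited table holds whole-number counts per gene, with totals between 17900227 and 20337329 in the light damage libraries and between 14652535 and 20699236 in the controls. The light dose, the time after exposure, and the sex and age of the animals are not given in the labels. Nothing in the labels says that the libraries came from separate animals, so p-values measure the spread between these libraries. How much of it is technical is not known. Light damage replicates 1 and 2 had 17174 and 20414 Xist counts, and replicates 3 to 5 had 6, 4 and 1. These counts argue against 1 animal as the source of all light damage libraries. They leave open whether the spread between controls is technical. Positions are not printed because the gene names were taken from an annotation of another genome build than the one named in the submitters' processing notes.

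The light damage libraries were not alike. Xist, the noncoding RNA that silences an X chromosome in female cells, had 17174 counts in light damage replicate 1 and 20414 in replicate 2. In the other 8 libraries it had between 1 and 9 counts. Lens genes followed the same division. The score of the lens list, the mean log2 CPM of its 12 tested genes centred over all libraries, was 5.49 and 4.81 in light damage replicates 1 and 2. It lay between -0.86 and 0.83 in light damage replicates 3 to 5 and between -3.15 and -0.74 in the controls. The high-Xist libraries belong to the light damage group alone, so no comparison within them was possible. Among the 8 low-Xist libraries, 3 light damage against 5 control, 129 genes were higher and 271 lower, against 896 and 1323 with all 10 libraries. The first principal component held 33.6% of the variance. Light damage libraries lay between -4.91 and 37.7 on it, with replicates 1 and 2 at the upper end, and controls lay between -23.1 and -13.4.

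**Figure D1:**
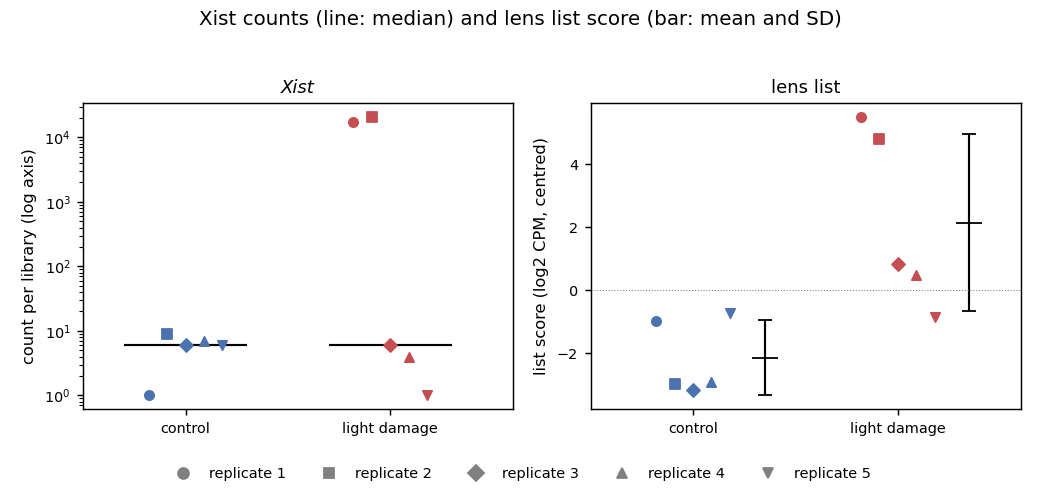
Xist counts on a log axis, with the median of each group as a line, and the lens list score in log2 CPM centred over all libraries, with mean and SD as bars, for 5 control and 5 light damage libraries. Light damage replicates 1 and 2 had 17174 and 20414 Xist counts and lens scores of 5.49 and 4.81, above every other library on both measures.

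In light-damaged retina 7 of 26 immediate early genes, which are induced within minutes of neuronal activity or stress, were lower, and so were 6 of 40 rod genes and 4 of 21 genes of the photoreceptor synapse. Higher were 12 of 27 markers of Müller glia, 10 of 22 of bipolar cells, 7 of 22 of amacrine cells and 9 of 32 genes of the oxidative stress response. In the low-Xist libraries alone 3, 4, 2 and 3 of these rose. Nr4a3 (ENSMUSG00000028341), an orphan nuclear receptor, averaged 2.32 ± 0.487 CPM in light damage and 9.86 ± 1.88 CPM in control (SD, n = 5 each). Its log2 fold change was -2.09 (SE 0.17, adjusted p = 9.36e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Müller glial Dkk3, a secreted modulator of Wnt signaling, averaged 998 ± 108 CPM against 719 ± 65.0 CPM. Its log2 fold change was 0.47 (SE 0.08, adjusted p = 0.00309 by the same quasi-likelihood test of edgeR).

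Of 16852 genes tested with edgeR's quasi-likelihood test, 896 were higher and 1323 lower in light damage at a Benjamini-Hochberg adjusted p under 0.05. Most changes were small. A log2 fold change over 1 was reached by 25 of the higher genes, and one under -1 by 90 of the lower genes. Tested against a log2 change of 0.5, 7 genes remained, each of them lower: Nr4a3, Egr4, Slc17a2, Fos, Fabp4, Nr4a1 and Sik1, the last named after its values were seen. With library totals alone in place of TMM scaling, 1147 genes were higher and 912 lower, so the balance between rises and falls depends on the scaling. The 2219 calls fell to 1168 without light damage replicate 1, 1305 without replicate 2, 1120 without replicate 3, and 1463 without control replicate 5.

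Of the 26 immediate early genes tested, 7 fell, 1 rose and the rest did not pass. Adjusted over the list alone, 9 fell and 1 rose. Nr4a3 fell furthest. Fos, a subunit of the AP-1 transcription factor, averaged 21.4 ± 3.27 CPM in light damage and 57.0 ± 10.1 CPM in control (SD, n = 5 each). Its log2 fold change was -1.41 (SE 0.12, adjusted p = 0.000152 by edgeR's quasi-likelihood test). Nr4a1 averaged 31.5 ± 1.99 against 69.4 ± 12.8 CPM, a log2 fold change of -1.14 (SE 0.10). Egr1, a zinc finger transcription factor, averaged 22.7 ± 10.9 against 63.9 ± 13.1 CPM, a log2 fold change of -1.49 (SE 0.32). Dusp1, a phosphatase of MAP kinases, fell by 0.44 on the log2 scale, and Egr3 and Nr4a2, named after their values were seen, also fell. Ier5 went the other way, with a log2 fold change of 0.40 (SE 0.09). Egr4, outside the list, fell by 1.65 on the log2 scale. The list as a whole was lower (camera, adjusted p = 0.000828; adjusted p = 0.49 with an estimated correlation). Its score was lower in each light damage library than in each control library, with an exact two-sided permutation adjusted p of 0.045. The median log2 fold change over the list was -0.31, -0.18 without light damage replicates 1 and 2, and -0.08 without control replicate 3. Egr1 lost its call without light damage replicate 2 (adjusted p = 0.056 by edgeR's quasi-likelihood test).

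**Figure D2:**
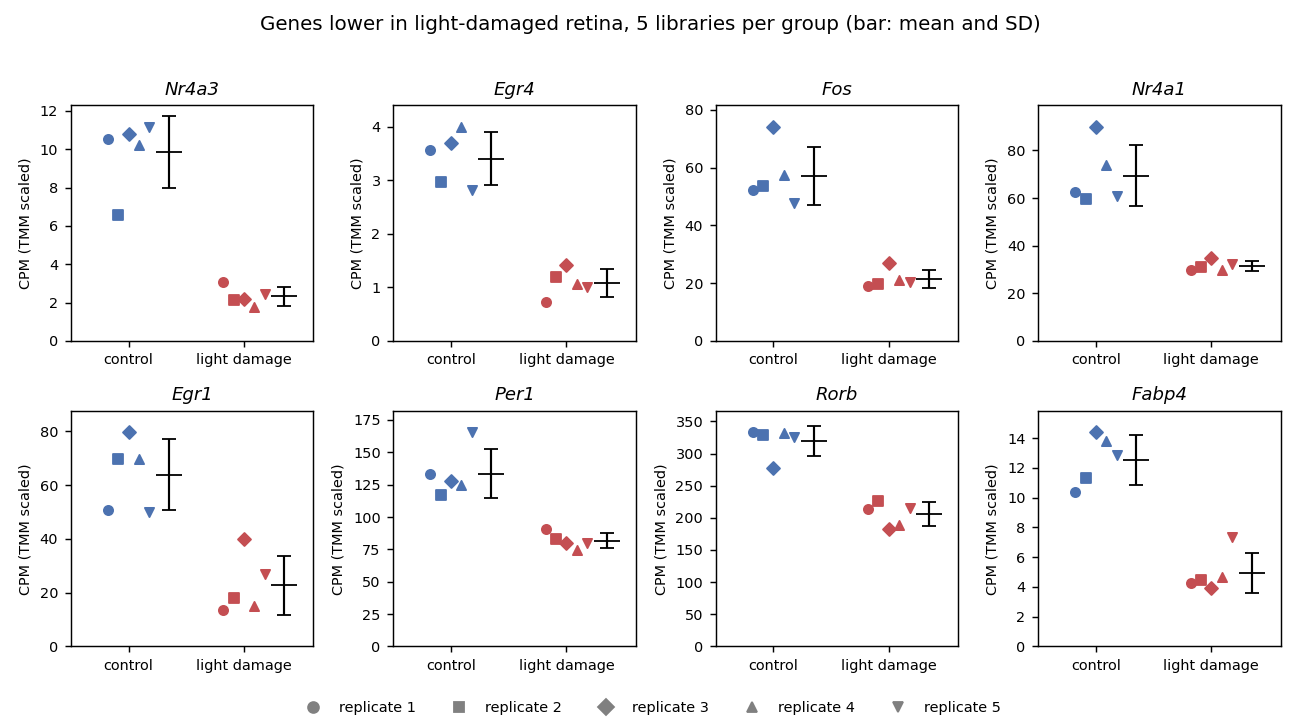
CPM after TMM scaling of 8 genes in 5 control and 5 light damage libraries, 1 marker shape per replicate number, with mean and SD as bars. Light damage values lay below every control value for each gene; the group means of Nr4a1 were 31.5 and 69.4 CPM.

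Of the 20 tested genes of the circadian clock, 5 fell and the rest did not pass; adjusted over the list alone, 5 fell and 1 rose. Per1, a repressor of the clock, averaged 81.7 ± 5.99 CPM in light damage and 134 ± 18.7 CPM in control (SD, n = 5 each), a log2 fold change of -0.71 (SE 0.08, adjusted p = 0.000391 by edgeR's quasi-likelihood test). Rorb, a nuclear receptor needed for rod development, averaged 206 ± 18.9 against 320 ± 23.9 CPM, a log2 fold change of -0.64 (SE 0.07). Per3 fell by 0.34 and Rora by 0.24 on the log2 scale. The list itself was not called (camera, adjusted p = 0.29), and its median log2 fold change, 0.01, and its mean, -0.09, differed in sign. Rora lost its call in 7 of the 10 fits that left out a library, among them the fit without light damage replicate 3 (adjusted p = 0.112 by edgeR's quasi-likelihood test).

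Among the other genes picked for the largest falls without overlap between the groups, Fabp4, a fatty acid binding protein, averaged 4.94 ± 1.38 CPM in light damage and 12.6 ± 1.69 CPM in control (SD, n = 5 each). Slc17a2, a sodium-dependent phosphate transporter, fell by 1.63, the coagulation factor gene F11 by 1.26, the glypican Gpc2 by 1.14 and Zan by 1.13 on the log2 scale. Adjusted p by edgeR's quasi-likelihood test lay between 0.000352 for Fabp4 and 0.00724 for F11, and each of these 5 genes kept its call without any single library. Without light damage replicates 1 and 2, F11 had an adjusted p of 0.0611 by the same test of edgeR.

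Among called genes without overlap between the groups, the 10 that rose most were each highest in light damage replicates 1 and 2, the lens gene Cryba4 first. Cryba4, a beta crystallin of the lens, averaged 68.0 ± 96.5 CPM in light damage and 0.64 ± 0.828 CPM in control (SD, n = 5 each). Its log2 fold change was 6.71 (SE 1.84, adjusted p = 0.0486 by edgeR's quasi-likelihood test), and 2.88 without replicates 1 and 2. All 12 tested lens genes had positive fold changes and 4 rose, the crystallins Crybb2, Cryba1 and Cryba4 and the homeobox gene Hmx1. Adjusted over the list alone, 12 rose. Hmx1 was not highest in light damage replicates 1 and 2. It had 30.5 and 28.1 CPM there and between 30.4 and 33.7 CPM in replicates 3 to 5. The lens list was called (camera, adjusted p = 6.18e-08; adjusted p = 0.435 with an estimated correlation). Sod3, an extracellular superoxide dismutase, rose by a log2 fold change of 2.21, Slc13a4, a sulfate transporter, by 1.90, Colec12, a scavenger receptor, by 1.63, Rab38, a small GTPase of melanosome transport, by 1.56, and Arsi, a sulfatase, by 1.51. Without light damage replicates 1 and 2 these values were 1.27, 1.06, 0.85, 1.14 and 0.63. Mgst1, Ism2, Ppfibp2 and Cpq rose by between 1.02 and 1.08, and without those libraries their log2 fold changes lay between 0.50 and 0.69. Cryba4, Slc13a4, Mgst1, Arsi, Sod3 and Ism2 lost their calls in 9, 8, 7, 6, 5 and 3 of the 10 fits that left out a library, each of them without light damage replicate 2 and without control replicate 5. The highest adjusted p for them were 0.102, 0.0849, 0.066, 0.0973, 0.0669 and 0.0871 by edgeR's quasi-likelihood test. Crybb2 and Cryba1 lost theirs in 8 of these fits each. Among rises with overlap between the groups, Crybb2 and Cryba1 had log2 fold changes of 7.48 and 7.76. Mfap4, Gpx3 and Penk, an opioid precursor of amacrine cells, were named after their values were seen. They also overlapped, with log2 fold changes of 3.55, 3.38 and 2.50. Without light damage replicates 1 and 2 these were 1.99, 1.85 and 1.86, and the calls were lost in 9, 9 and 7 of the 10 fits that left out a library, with adjusted p up to 0.0964 and 0.0621 for Mfap4 and Penk without control replicate 5 and 0.0991 for Gpx3 without light damage replicate 1, by edgeR's quasi-likelihood test.

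Müller glia, the radial glia of the retina, had 12 of 27 tested markers higher and none lower, and 15 higher adjusted over the list alone. Rlbp1, the retinaldehyde binding protein of the visual cycle, averaged 474 ± 34.9 CPM in light damage and 366 ± 36.6 CPM in control (SD, n = 5 each), a log2 fold change of 0.38 (SE 0.08, adjusted p = 0.00612 by edgeR's quasi-likelihood test). Prdx6, a peroxiredoxin, rose by a log2 fold change of 0.37, Hes1, a target of Notch, by 0.44, and Clu, a secreted chaperone, by 0.66. Of 22 bipolar cell markers 10 rose and none fell, and 12 rose adjusted over the list alone. Vsx1, a homeobox gene of bipolar cells, rose by 0.47, Gng13, a G protein subunit, by 0.38 and Bhlhe23 by 0.33 on the log2 scale. Of 22 amacrine cell markers 7 rose and none fell, and 12 rose adjusted over the list alone. Slc32a1, the vesicular GABA transporter, averaged 118 ± 9.20 against 92.5 ± 6.79 CPM, and Gad1, a GABA synthesising enzyme, 308 ± 11.7 against 249 ± 26.9 CPM, log2 fold changes of 0.35 and 0.31. C1ql2 and Dab1 rose by 0.34 and 0.25. Each of the 11 genes named here kept its call without any single library. All 3 lists were called by camera, with adjusted p = 8.37e-10 for Müller glia, 3.35e-06 for bipolar cells and 3.17e-06 for amacrine cells. The adjusted p with an estimated correlation were 0.414, 0.466 and 0.414. The 3 scores were higher in each light damage library than in each control library, each with an exact two-sided permutation adjusted p of 0.045. In the low-Xist libraries alone, 3 Müller glial, 4 bipolar and 2 amacrine markers rose.

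Fewer markers of other retinal neurons were called. Of 11 horizontal cell markers 2 rose, Calb1 and Sept4 with log2 fold changes of 0.27 and 0.19, and the list was called (camera, adjusted p = 0.0486; adjusted p = 0.471 with an estimated correlation). That call was lost in 6 of the 10 fits that left out a library, with adjusted p up to 0.162 without control replicate 1. Calb1 lost its call without light damage replicate 1 (adjusted p = 0.0546 by edgeR's quasi-likelihood test), and Sept4 in 7 of these fits. Of 24 ganglion cell markers 0 passed by edgeR's quasi-likelihood test, 4 had an unadjusted p under 0.05 and DESeq2 called 2 (camera on the list, adjusted p = 0.0544; called without control replicate 1 at 0.000326, control replicate 4 at 0.0451 or light damage replicate 4 at 0.0211, without a filter on low counts at 0.0313 and with library totals alone at 0.0361; adjusted p = 0.683 with an estimated correlation). Of 18 cone markers 2 fell, Grk1, which is also in the rod list, and Arr3, the cone arrestin (camera on the list, adjusted p = 0.301).

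Of 40 rod photoreceptor genes, 6 fell and 1 rose, and the counts were the same adjusted over the list alone. Grk1, a kinase of rod phototransduction, averaged 1455 ± 81.7 CPM in light damage and 1930 ± 197 CPM in control (SD, n = 5 each), a log2 fold change of -0.41 (SE 0.08, adjusted p = 0.00476 by edgeR's quasi-likelihood test). Abca4, the retinoid transporter of outer segments, fell by 0.44, Gucy2e, the guanylate cyclase of photoreceptors, by 0.37 and Impg1, a proteoglycan of the matrix around photoreceptors, by 0.37 on the log2 scale. Sag, rod arrestin, rose by a log2 fold change of 0.29, a call lost in 8 of the 10 fits that left out a library, with an adjusted p of 0.10 without light damage replicate 3 by edgeR's quasi-likelihood test. The rod list was lower (camera, adjusted p = 0.000377; adjusted p = 0.683 with an estimated correlation). Rod scores of the groups overlapped, -0.08 ± 0.12 against 0.08 ± 0.17 (SD, n = 5 each), with an exact two-sided permutation adjusted p of 0.306. Of 21 genes of the photoreceptor synapse, 4 fell and 1 rose, and 7 fell and 1 rose adjusted over the list alone. Cacna1f, the calcium channel of photoreceptor terminals, averaged 324 ± 35.3 against 468 ± 43.2 CPM, a log2 fold change of -0.53 (SE 0.08, adjusted p = 0.00162 by edgeR's quasi-likelihood test). Cacna2d4, an auxiliary channel subunit, fell by 0.32 and Elfn1, a synaptic adhesion protein, by 0.29, while Cplx3, a complexin, rose by 0.32. The synapse list was lower (camera, adjusted p = 0.000763; adjusted p = 0.414 with an estimated correlation), and its scores did not overlap between groups, with an exact two-sided permutation adjusted p of 0.045. In the low-Xist libraries alone, 2 rod genes and 1 synapse gene fell. With the replicate number as a block, 15 rod genes fell and 1 rose.

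**Figure D3:**
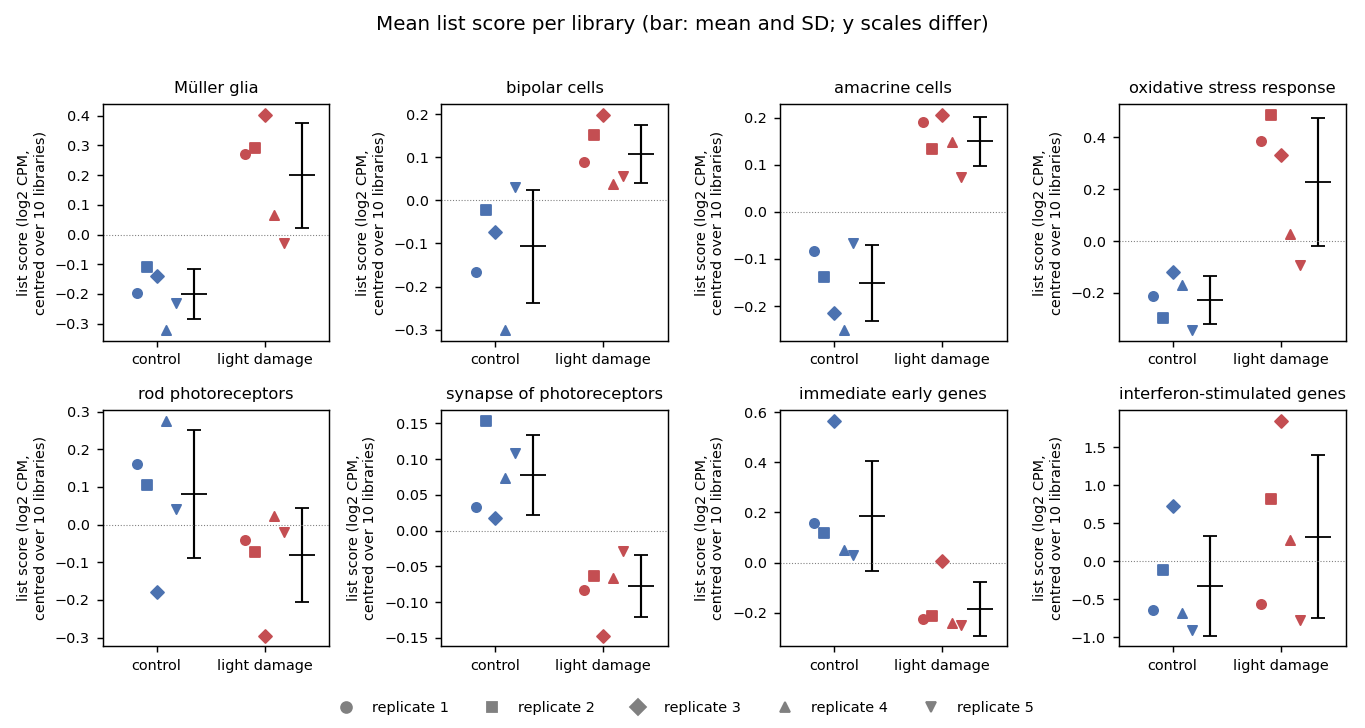
Mean score of 8 gene lists per library, in log2 CPM centred over all 10 libraries, with mean and SD as bars and a separate y scale for each list. Light damage and control libraries do not overlap for Müller glia, bipolar cells, amacrine cells, the oxidative stress response, the photoreceptor synapse and immediate early genes; they overlap for rods and for interferon-stimulated genes, where light damage replicate 3 is highest at 1.85.

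Of 32 genes of the oxidative stress response, 9 rose and none fell, and 11 rose adjusted over the list alone. Sod1, a superoxide dismutase, averaged 120 ± 3.24 CPM in light damage and 97.8 ± 7.60 CPM in control (SD, n = 5 each), a log2 fold change of 0.30 (SE 0.06, adjusted p = 0.00538 by edgeR's quasi-likelihood test). Mt1, a metallothionein, rose by a log2 fold change of 0.62 and Gsta4, a glutathione transferase, by 0.50. Sod3 is also in this list. The list was called (camera, adjusted p = 1.11e-07; adjusted p = 0.414 with an estimated correlation), and its scores did not overlap, with an exact two-sided permutation adjusted p of 0.045. Scores were 0.39 and 0.49 in light damage replicates 1 and 2, which also had the highest lens scores, and between -0.09 and 0.33 in replicates 3 to 5. In the low-Xist libraries alone, 3 members rose. Of 29 genes of the unfolded protein and heat shock response 5 rose, among them Herpud1 with a log2 fold change of 0.23 and Hspe1 with 0.32 (camera on the list, adjusted p = 0.0334; adjusted p = 0.622 with an estimated correlation). The call of that list was lost in 4 of the 10 fits that left out a library, with an adjusted p of 0.117 without control replicate 5, and Hspe1 lost its call without light damage replicate 2 (adjusted p = 0.0508 by edgeR's quasi-likelihood test). Of 31 genes of the visual cycle and pigment epithelium 3 rose, Rlbp1, also a Müller glial marker, and Rrh and Mertk, with log2 fold changes of 0.28 and 0.41 (camera on the list, adjusted p = 2.02e-05; adjusted p = 0.466 with an estimated correlation). Its scores were highest, 0.90 and 0.55, in light damage replicates 1 and 2. Without light damage replicate 3 neither Rrh (adjusted p = 0.0678) nor Mertk (adjusted p = 0.0934) passed edgeR's quasi-likelihood test.

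Few inflammatory and immune genes passed the test without a replicate block. Of 35 interferon-stimulated genes 0 passed by edgeR's quasi-likelihood test, 1 had an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. Their median log2 fold change was 0.86, and the list was called (camera, adjusted p = 0.000536; adjusted p = 0.683 with an estimated correlation). Scores were 0.32 ± 1.07 in light damage and -0.32 ± 0.66 in control (SD, n = 5 each), with an exact two-sided permutation adjusted p of 0.416. Light damage replicate 3 had the highest score, 1.85, and control replicate 3 had 0.73. Without light damage replicate 3 the median was 0.30 and the call was lost (camera, adjusted p = 0.0786). With the replicate number as a block, 17 interferon-stimulated genes, 7 microglial and macrophage markers and 6 antigen presentation genes were higher. Of 29 markers of microglia and macrophages, all had positive fold changes and 2 rose, Csf1r, the receptor for colony stimulating factor, by a log2 fold change of 0.71 (SE 0.15) and Cd63 by 0.48 (SE 0.14); adjusted over the list alone, 1 rose. Their list was called (camera, adjusted p = 3.17e-06; adjusted p = 0.511 with an estimated correlation), with the highest scores, 1.06 and 0.75, in light damage replicates 3 and 2. Cd63 lost its call in 8 of the 10 fits that left out a library, with an adjusted p of 0.0978 without light damage replicate 3 by edgeR's quasi-likelihood test. Of 19 genes of antigen presentation H2-M3 alone rose, by a log2 fold change of 0.94, and its call was lost in 4 of those fits. The antigen presentation list was called (camera, adjusted p = 0.00135; adjusted p = 0.683 with an estimated correlation), and its median log2 fold change of 0.76 became 0.34 without light damage replicate 3. Of 12 chemokine and cytokine genes 0 passed by edgeR's quasi-likelihood test, 5 had an unadjusted p under 0.05 and DESeq2 called 2 (camera on the list, adjusted p = 0.0183, and 0.0687 without light damage replicate 3; adjusted p = 0.49 with an estimated correlation). Of 37 genes of reactive gliosis Egr1 alone fell and none rose, while the list was called higher (camera, adjusted p = 0.0101; adjusted p = 0.683 with an estimated correlation). That call was lost without light damage replicate 2 (0.0577), light damage replicate 3 (0.0738) or control replicate 4 (0.0668). Gfap, the intermediate filament of reactive glia, named after its values were seen, averaged 94.2 ± 34.0 CPM in light damage and 90.0 ± 45.4 CPM in control (SD, n = 5 each), a difference smaller than the spread between libraries.

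The genes named in the series title had low counts. P2rx7 (ENSMUSG00000029468), the ATP-gated channel, had between 10 and 30 counts per library and averaged 1.10 ± 0.307 CPM in light damage and 0.825 ± 0.20 CPM in control (SD, n = 5 each). Its log2 fold change was 0.41 (SE 0.27, adjusted p = 0.322 by edgeR's quasi-likelihood test). Sting1 (ENSMUSG00000024349), the adaptor of cytosolic DNA sensing, averaged 1.51 ± 0.715 against 0.972 ± 0.473 CPM. Its log2 fold change was 0.62 (SE 0.36, adjusted p = 0.255 by edgeR's quasi-likelihood test). Cgas (ENSMUSG00000032344), the DNA sensor, had between 1 and 7 counts per library, was below the filter on low counts, and averaged 0.266 ± 0.0806 against 0.247 ± 0.12 CPM (exact two-sided permutation p = 0.786). Sting1 ranged from 8 to 50 counts per library. No difference in these 3 genes passed a test here. Of 19 tested genes of the cGAS-STING pathway, 1 rose and 2 fell, with the same counts adjusted over the list alone. Trim32, a ubiquitin ligase, had a log2 fold change of 0.30 (SE 0.06, adjusted p = 0.00531 by edgeR's quasi-likelihood test). Samhd1, a nucleotide hydrolase, fell by 0.25 and Irf3, the transcription factor downstream of Sting1, by 0.26 on the log2 scale. The list was not called (camera, adjusted p = 0.851), and its median log2 fold change was 0.08. Samhd1 lost its call in 4 and Irf3 in 7 of the 10 fits that left out a library, with adjusted p of 0.0585 and 0.103 without light damage replicates 1 and 3 by edgeR's quasi-likelihood test.

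Of 22 purinergic receptor and ectonucleotidase genes, 3 rose and 1 fell, with the same counts adjusted over the list alone. Panx1, an ATP-releasing channel, rose by a log2 fold change of 0.41 (SE 0.12), Adora2b, an adenosine receptor, by 0.58 (SE 0.18) and P2rx6, an ATP-gated channel, by 0.51 (SE 0.16). Slc17a9, the vesicular nucleotide transporter, had 0.639 ± 0.399 CPM in light damage and 1.55 ± 0.276 CPM in control (SD, n = 5 each), a log2 fold change of -1.28. Their adjusted p by edgeR's quasi-likelihood test lay between 0.0213 and 0.0492, and the 4 genes lost their calls in 5, 9, 9 and 3 of the 10 fits that left out a library, each of them without light damage replicates 1, 2 and 3. The highest adjusted p in these fits were 0.0827, 0.0958, 0.14 and 0.0607 by edgeR's quasi-likelihood test. The list was not called (camera, adjusted p = 0.138). Of 8 inflammasome and pyroptosis genes Ninj1, a mediator of membrane rupture, alone rose, by a log2 fold change of 0.42 (SE 0.10, adjusted p = 0.0146 by edgeR's quasi-likelihood test), and the list was not called (camera, adjusted p = 0.55). Of 28 cell death genes Cdkn1a, a target of p53, alone rose, from 3.08 ± 0.581 to 5.14 ± 0.691 CPM (SD, n = 5 each), a log2 fold change of 0.74 (SE 0.16, adjusted p = 0.00889 by edgeR's quasi-likelihood test), and the list was not called (camera, adjusted p = 0.374). Of 17 complement genes Clu rose and Cd46, a membrane cofactor, fell by 0.57 on the log2 scale. The complement list was not called (camera, adjusted p = 0.0715), but was called without light damage replicate 5 (0.00456), light damage replicate 4 (0.0229), control replicate 3 (0.0208) or control replicate 2 (0.0481), and without a filter on low counts (0.038). The list had an adjusted p = 0.683 with an estimated correlation.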

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

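Of the tests of explanations in this part, those of the high-Xist libraries and of the time of day were chosen after the result was seen. That of GC content and transcript length was set down before its result was seen, but its fit was chosen after seeing the data. Single libraries were compared with the others of their group by the gap to the nearest library over the range of the group. Of 222 sets of 5 values, 14 had a library farther out than Dixon's 95% limit of 0.71, where chance gives about 1 in 20. Control replicate 3 lay apart in 5 of them. Its CPM was above the other controls for Rtp4 (3.04 against 0.891 to 1.31) and Mt1 (40.7 against 28.1 to 31.7), and below them for Rorb (277 against 326 to 333). Its score was above the other controls for immediate early genes (0.567 against 0.0305 to 0.156) and for reactive gliosis (0.588 against -0.434 to -0.154). Light damage replicate 3 also lay apart in 5. Its CPM was above the other light damage libraries for Fos (27.1 against 19.0 to 21.0), Sag (5750 against 4860 to 5090), Hsph1 (82.7 against 74.7 to 76.4) and Mertk (14.1 against 10.2 to 11.1), and so was its score for immediate early genes (0.00521 against -0.248 to -0.214). In other libraries, Nr4a3 was 6.56 CPM in control replicate 2 against 10.2 to 11.2 in the other controls, Gsta4 19.5 CPM in control replicate 1 against 15.3 to 16.5, and Mertk 6.79 CPM in control replicate 4 against 8.90 to 9.18. Fabp4 was 7.35 CPM in light damage replicate 5 against 3.93 to 4.65 in the other light damage libraries.

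The fall of 7 of 26 immediate early genes was weighed because it held 4 of the 10 largest falls picked by the naming rule, Nr4a3, Egr1, Fos and Nr4a1. These 7 had a median log2 fold change of -1.14. Without light damage replicates 1 and 2 the median was -1.10 and 4 members kept their call, with 3 against 5 libraries left to test. The fall of these 7 was thus not confined to those libraries, but the 7 were chosen as called in the same data. The median over all 26 tested genes shrank to -0.18 without those libraries. With the trends of GC content and transcript length removed the median of the 7 was -1.17 and 7 kept their call, which argues against such a bias. Collection at another time of day stays open and cannot be told apart from the damage. Clock genes that peak with Per and Dbp had a median of 0.07 and those in antiphase 0.03. The former set left out Per1, which had a log2 fold change of -0.71. Within that set Per3 fell by 0.34, while Dbp had a log2 fold change of 0.29 and was not called. An effect of light damage on neuronal activity may also underlie the fall, and no test here separates it from handling at collection.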

How the results depend on the processing

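The fits without or with a term for the high-Xist libraries, with the lens score or with trends removed, and the permutation of scores were chosen after seeing the data. Each of the 2219 called genes, where tested, kept its direction under every scaling, tool, filter and left-out library; 2218 kept it with the lens covariate and 2215 with trends removed. Called totals were 2911 by DESeq2, 2009 by limma-voom, 2217 with DESeq2 size factors, 2223 with upper quartile scaling, 2110 without a filter, 2186 without robust dispersion and 2397 with trends removed. Higher genes with a log2 fold change over 1 moved from 25 to 79 by DESeq2, 16 by limma-voom and 63 without robust dispersion. With at least 10 CPM in 5 libraries, fewer genes were tested and 7 higher and 6 lower passed that fold. Against a log2 change of 0.5, glmTreat called 0 higher and 7 lower genes, 0 and 6 of them past a fitted change of 1, and at an unadjusted p under 0.05 it had 130 and 311. Without the high-Xist libraries 129 genes were higher and 271 lower (5 and 36 past a log2 change of 1), with 3 light damage libraries left; leaving out other pairs of light damage libraries left between 158 and 2082 calls. A term for these libraries gave 258 higher and 439 lower (6 and 46). With the lens score as a covariate 1 gene was higher and 7 lower (0 and 3); the score was itself higher in light damage, and the cause was not tested.

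Leaving out 1 library gave between 394 and 1342 higher and between 726 and 1643 lower genes, and between 6 and 81 higher and 59 and 141 lower past a log2 change of 1. Lists called higher, 13 by camera, lay between 8 and 16, the lowest without light damage replicate 3. With an estimated correlation 0 lists were higher and 0 lower, with 4 at an unadjusted p under 0.05. By fry 5 were higher and 2 lower, and by exact permutation of scores 4 and 2; the cause was not tested. The cGAS-STING list was not called in any of these fits. Its adjusted p by camera lay between 0.651 and 0.965, and its direction turned without light damage replicate 2 (0.938), light damage replicate 3 (0.828) or control replicate 1 (0.909). Of 76 called genes that the naming rule picked, between 55 and 71 kept their call without 1 library, 26 without the high-Xist libraries and 5 with the lens covariate.

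With the replicate block, 1431 genes were higher and 1854 lower, 40 of the former past a log2 change of 1, and 72 of those 76 genes kept their call. Interferon-stimulated genes moved from 0 to 17 higher (camera on the list, adjusted p = 5.28e-11), antigen presentation genes from 1 to 6 higher and rod genes from 6 to 15 lower. The complement and ganglion cell lists were called with it (camera, adjusted p = 0.00422 and 0.0408). The numbers were not taken to pair the libraries: deviations of same-numbered libraries correlated between 0.0522 and 0.316 across genes, which are not independent replicates, and 2 light damage and 3 control libraries correlated best with their own number.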

Other observations

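Of 25 genes of glycolysis and hypoxia 3 rose and 2 fell, also adjusted over the list alone. Genes in this paragraph were named after their values were seen. Hk2, a hexokinase enriched in photoreceptors, averaged 319 ± 27.8 CPM in light damage and 456 ± 32.6 CPM in control (SD, n = 5 each), a log2 fold change of -0.51, and Pfkp fell by 0.34. Aldoc, Ldhb and Pfkm rose by 0.26, 0.28 and 0.25. The list itself was not called (camera, adjusted p = 0.264). Of 21 survival factors and receptors, Ptn rose by 0.61 and Cntfr by 0.26, and Lifr fell by 0.27 (camera on the list, adjusted p = 0.352). Extracellular matrix genes had 2 of 21 higher, among them Sparc with a log2 fold change of 0.65. Proliferation genes had 2 of 25 higher, Pcna and Ccne1, and Ccna2 lower. One gene each changed among oligodendrocyte markers (Cnp, higher) and NF-kB genes (Rel, lower). In the vascular, blood, lipid metabolism and mitochondrial lists edgeR's quasi-likelihood test called 0 genes. There 3, 0, 9 and 0 had an unadjusted p under 0.05, and DESeq2 called 2, 0, 3 and 0. None of these 10 lists was called by camera. The cornea list had 3 tested genes, of which Aldh1a1 came closest to a call, with a log2 fold change of 0.74 (adjusted p = 0.0585 by edgeR's quasi-likelihood test). Lists of neutrophils and lymphocytes and of sex-linked transcripts had 0 tested genes.

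Noncoding transcripts had lower scores in light damage. Of 1871 long noncoding and unassigned transcripts 7 rose and 230 fell, while of 14172 protein-coding genes 877 rose and 1062 fell. In the low-Xist libraries alone the noncoding counts were 0 and 52. The mean log2 CPM of noncoding relative to coding genes was below every control library in each light damage library (exact two-sided permutation p = 0.00794). Counts by transcript length were not compared by a test. Among the 3361 genes with the longest transcripts 55 rose and 522 fell, and among the 3362 with the shortest 224 rose and 144 fell. Prss56 and Serpine3, named after their values were seen, varied widely within groups. Prss56, a serine protease, was between 95.9 and 273 CPM in light damage replicates 3 to 5 and 234 CPM in control replicate 3, and between 0.73 and 6.26 CPM in the other 6 libraries. Serpine3 followed the same division, between 19.2 and 35.7 CPM in those 4 libraries and between 0.57 and 2.82 CPM in the others.

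Chance alone is unlikely to give the number of called genes: 1 of 100 splits of the libraries, the real one, gave as many as 2219, and the highest other split gave 44. The other splits mix the groups, so a difference between the groups widens their spread and lowers their calls. The count does not tell light damage from other differences between the groups, such as the high-Xist libraries. Chance cannot be excluded for the number of called lists, since 24 of 100 splits gave as many as the real 16, and the highest other gave 23. Both splits that called 23 lists had light damage replicates 1, 2 and 3 and control replicate 3 on the same side.

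For the rise of the lens list, of the tests that follow, that of light damage replicates 3 to 5 was set down before its result was seen and the other 2 were chosen after the result was seen. The markers were 9 tested genes of the anterior eye outside the lens list and the naming rule, such as Optc, Best2 and Slc26a4. Of these, 5 averaged at least 1 CPM in control retina, as did 6 of the 12 lens genes. The median log2 difference of the 9 markers between light damage replicates 1 and 2 and the other 8 libraries was 2.93 (quartiles 2.58 and 3.55), with Aqp1 at 0.06 and Foxc1 at 0.55 the lowest. Lens genes summed to at least 4850 CPM there against at most 230 CPM elsewhere, which is what lens and anterior eye tissue in those dissections would give. Against the controls that median was 2.97, which argues against crystallin induction within the retina as the whole cause. Whether the list was also higher in light damage replicates 3 to 5 stays open, since their scores lay 2.30 above the controls with an exact two-sided permutation p of 0.0536.

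For the rise of 29 Müller glial, bipolar and amacrine markers, all tests were chosen after the result was seen. Group differences in the scores of all 6 lists of other retinal cell types, without rod genes, were 0.40 for Müller glia, 0.30 for amacrine, 0.21 for bipolar, 0.13 for horizontal and 0.09 for ganglion cells and -0.05 for cones. The amacrine value includes Penk, with a log2 fold change of 2.50, while the next highest member, Npy, had 0.50. The spread of these group differences, with each library centred over the 6 lists, shows that the lists did not move alike (exact permutation p = 0.00794). A lower share of rods alone would raise them alike only if each marker were absent from rods and other cells. That was not tested, so the spread does not decide whether a lower share of rods underlies the rise. In light damage replicates 3 to 5 the mean score of the 3 lists lay 0.28 above the controls, against 0.30 with all 5. The rise was thus not confined to replicates 1 and 2. The exact two-sided permutation p of 0.0179 adds nothing, because no score of these lists overlapped between the groups. Without replicates 1 and 2, 9 of the 29 called members kept their call. With the lens score as a covariate, 0 markers of these lists were called higher. With the trends of GC content and transcript length removed the 29 called members kept a median of 0.33 against 0.36, 25 of them called. A response of glia and inner neurons to light damage may explain the rise, as a hypothesis found and tested on the same data.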
